A study of Mus musculus with 12 samples.

How the data were processed

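Gene expression was measured by RNA sequencing of total RNA from isolated mouse islets in 12 libraries, 2 mice in each of 6 groups. Islets of wild-type C57BL/6 mice were kept at low glucose (2G), at 11 mM glucose for 4 h (11G), at 11 mM glucose for 4 h with diazoxide (11G+D), or at 11 mM glucose for 4 h with FK506 (11G+FK). Islets with channelrhodopsin-2 (ChR2), a channel opened by light, in their β cells were kept without light or under light for 40 min. The light came in cycles with 5 min off in each, and the labels give no glucose concentration for these islets. The labels call the 2G islets untreated and give neither a concentration in mM nor a time. The comparisons of 11G and of 11G+D with 2G can therefore also hold the effect of incubation. Per the labels' protocols, islets were isolated with collagenase and a commercial provider made and sequenced the libraries. The aligner, the counting tool, the use of strand and the genome build are not given in the sources used here.

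The authors deposited 8 tables, each comparing 2 libraries of 1 mouse. Per the file headers, each table holds raw read counts and FPKM values per gene and library, the authors' normalized counts, a log2 fold change, a p-value and an adjusted p-value. The test behind the deposited p-values is not given in the sources used here, and each compares 1 library with 1 library. Within a column, the normalized counts deposited by the authors (a signal scaled per table) were a constant multiple of the raw counts. The 11G library of each mouse stands in 3 tables, and its counts differed at 0 genes between them. Gene names and coordinates were taken from the tables. Of the 24503 gene identifiers in the joined table, 24212 (98.8%) were found in GENCODE release M21, and 86.4% of those shared the chromosome and the start or end, 69.9% both ends. No gene lacked a name. Column codes were matched to samples through the condition headings and mouse numbers of the tables.

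Raw counts were joined into 1 table and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM normalization, filterByExpr (minimum count 10, minimum total count 15) and the mouse number as a block. The 8 wild-type libraries were fitted together (16087 genes, 3 residual degrees of freedom) and the 4 ChR2 libraries apart from them (15171 genes, 1 residual degree of freedom). These tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of the F statistic. The biological coefficient of variation was 16.2% in both fits. Log2 changes per mouse used log2 CPM (counts scaled to library size with TMM factors) with a prior count of 1. The numbers pair the samples because the labels give the same mouse number to islets under each condition. Deviations from the group means of libraries with the same mouse number correlated across genes by 0.15 to 0.46 in wild type and by 0.50 in ChR2.

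Before the data were examined, 25 gene lists were fixed, 8 of them markers of cell types and 17 of pathways or gene classes, as were the designs and the rule for named genes. The rule takes, per comparison, the 10 largest increases and the 10 largest decreases among genes past the threshold with the same direction in both mice and a mean of at least 1 FPKM. Where fewer pass, the rest are filled with the largest changes among genes with a mean of at least 5 FPKM, given as values. It adds up to 4 members of each list past its test or with a member past the threshold, and a fixed set (Ins1, Ins2, Gcg, Sst, Fos, Npas4, Egr1, Nr4a1, Txnip and Rcan1). Unnamed gene models are left out of the first part. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone. Some lists share genes, such as immediate early with CREB and cAMP responsive genes and glycolysis with hypoxia genes. Their tests are therefore not independent.

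Changes shared between comparisons were counted beside the number independent lists would share. Because 3 comparisons use the same 11G libraries, 20 simulations of unchanged groups gave the value that shared libraries alone produce, and correlations were also computed between mice, which share no library. For shared calls, 20 further simulations with the fitted dispersions kept the fitted changes of called genes in the selecting comparison and gave those of the other to random genes of similar level; these were added after the results were seen. Alternatives were a fit without the block, DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter at 10 CPM in 2 libraries, all 12 libraries in 1 fit, and leaving out each library in turn (for light within the fit of all 12 libraries). The acinar marker share as a covariate was added after the data were examined. The procedure was tested on simulated counts. For 11G against 2G it recovered 23.9% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 100% of those changed 4-fold over 15746 genes, with 6 false among 135 calls. For light against no light it recovered 29.9%, 73.1% and 98.5% over 14898 genes, with 3 false among 137 calls. With no change simulated, the quasi-likelihood test of edgeR called 0 genes in either. Each simulated gene had the dispersion of the trend and the same mean in both mice. These rates therefore do not cover genes that vary more than the trend or differ between mice.

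Library totals ran from 15196061 to 22892255 read counts. How far read depth and the spread between 2 mice each limit the precision of a gene's level was not separated. The plot of gene levels, sex-linked levels and shares of counts use raw library totals without TMM factors. Figures were drawn with matplotlib 3.10.9.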

Results

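RNA from isolated islets was sequenced to ask how electrical activity alters islet transcripts. There were 12 libraries in 6 groups, with 2 mice in each group. Wild-type islets were held at low glucose, at 11 mM glucose, at 11 mM glucose with diazoxide, which opens ATP-sensitive potassium channels and hyperpolarizes the membrane, or at 11 mM glucose with FK506, an inhibitor of the phosphatase calcineurin. β-cell-specific ChR2 islets were held without or under light. Total counts per library in mice 1 and 2 were 19210755 and 22892255 at 2G, 21992513 and 18606190 at 11G, 18938404 and 17357572 with diazoxide, 17795331 and 16375631 with FK506, 15196061 and 18982668 without light, and 20967614 and 19584565 under light. Ins2, which encodes insulin, took up to 7.59% of the counts of a library. Each log2 change is given ± its standard error from the edgeR fit, and an adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That standard error uses a spread estimated across the libraries and genes of a fit. It can therefore be smaller than the spread of 1 gene between the 2 mice. Genomic positions are as the tables give them, with no build named.

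The first comparison set 11G against 2G. Because the labels give no time for 2G, it can hold the effect of incubation as well as that of glucose. Changes called glucose changes below are those of 11G against 2G. Npas4, a transcription factor induced by neuronal activity, rose 45.4-fold (log2 change 5.51 ± 0.31, n = 2 mice), from 1.28 and 1.74 CPM (counts scaled to library size with TMM factors) at 2G to 77.3 and 60.1 CPM at 11G. Lbh, a transcriptional cofactor, rose 16.4-fold (4.04 ± 0.26), and Nr4a1, an orphan nuclear receptor, 9.71-fold (3.28 ± 0.31; 2.69 without 11G mouse 1 and 3.81 without 11G mouse 2). G6pc2, the islet glucose-6-phosphatase subunit, rose by 2.35 ± 0.32. Adora2b, an adenosine receptor, fell (-3.04 ± 0.24). By edgeR's quasi-likelihood test the adjusted p was 3.65e-05 for Npas4, 9.72e-05 for Lbh and 0.000355 for Adora2b. The files list Npas4 as ENSMUSG00000045903 on chromosome 19 (4984355 to 4989971) and Lbh as ENSMUSG00000024063 on chromosome 17 (72918305 to 72941942). Ins1, Ins2 and Gcg, which encode insulin and glucagon, did not pass the test, with log2 changes of 0.36 ± 0.31, 0.12 ± 0.39 and 0.43 ± 0.39. Nor did Txnip, a thioredoxin-binding protein (1.24 ± 0.35; 2.23 in mouse 1 and 0.39 in mouse 2; adjusted p 0.0748), or Rcan1, a calcineurin regulator (0.18 ± 0.17).

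In all, 778 of 16087 genes changed in 11G, 503 higher and 275 lower, of which 282 and 131 changed at least 2-fold. Beside those above, the largest increases were in Abhd16b, Spsb4, Rgs2, Klhdc8a, Rprml, Megf9 and Zdhhc22 (2.73 to 5.50). The largest decreases were in Ighm, Igkc, Reg2, Chp2, Hpgd, Syt8, Reg3b, Reg1 and Ccl21a (-5.52 to -2.95). Reads of the immunoglobulin and Reg families could be split between near-identical genes, so their values are uncertain. Some of these decreases also end near the floor. Over raw library totals, 11G mice 1 and 2 had 0.0909 and 0.0537 CPM for Igkc and 0.273 and 0 CPM for Ighm. Reg2 was at 0.0455 and 1.29 CPM and Ccl21a at 0 and 1.99 CPM. The sizes of these decreases therefore rest on few reads in at least 1 mouse. Without the mouse block 68 genes passed, 54 of them higher, and leaving out 1 library gave 1405 (2G mouse 1), 42 (11G mouse 1), 316 (2G mouse 2) or 157 (11G mouse 2). With all 12 libraries in 1 fit, 495 genes were higher and 447 lower, and with the acinar marker share as a covariate, most of which condition and mouse explain, 0 passed (928 at an unadjusted p under 0.05). Single libraries moved several of these values more than 1.5-fold. Without 2G mouse 1 Abhd16b was at 4.88, Spsb4 4.49, Chp2 -2.64, Syt8 -4.14, Reg2 -2.18, Reg3b -1.43 and Reg1 -2.0, and without 2G mouse 2 Spsb4 was at 6.19, Chp2 -4.05, Syt8 -2.08 and Reg3b -4.83. Without 11G mouse 1 Rgs2 was at 2.33, Ighm -8.56, Igkc -4.60 and Ccl21a -2.18, and without 11G mouse 2 Reg2 was at -6.90, Hpgd -4.45, Reg1 -4.85 and Ccl21a -8.89. Reg2, Syt8 and Reg3b passed in 1 of the 4 fits, and Hpgd and Ccl21a in 2.

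Several gene groups moved with glucose. Among CREB and cAMP responsive genes, 6 of 29 rose and none fell (10 when adjusted over the list alone), including Nr4a2 (2.53 ± 0.24) and Fosb (2.05 ± 0.34, 2.64 without 2G mouse 2); the adjusted p of camera was 4.21e-09, and adjusted p = 0.542 with an estimated correlation. Of 39 immediate early genes, 7 rose and 2 fell (12 and 5 adjusted over the list alone; medians 0.39 and -0.01 in mice 1 and 2; camera adjusted p 0.000612, adjusted p = 0.781 with an estimated correlation), whereas Fos (1.18 ± 0.39) and Egr1 (0.11 ± 0.18) did not pass. Among β-cell identity and hormone genes 6 of 35 rose (7 higher and 2 lower adjusted over the list alone). They included the transcription factors Neurod1 (1.51 ± 0.25) and Pax6 (1.26 ± 0.21) and the prohormone convertase Pcsk1 (1.38 ± 0.30). Over the fits that leave out 1 library Neurod1 ran from 1.23 to 1.83, Pax6 from 1.08 to 1.46 and Pcsk1 from 1.07 to 1.63. Among exocytosis genes 4 of 29 rose, including Unc13a (1.18 ± 0.15) and Syt4 (1.14 ± 0.21), and 2 of 25 cholesterol synthesis genes rose, including Msmo1 (0.95 ± 0.20), each list with 6 when adjusted over the list alone. Camera's adjusted p for these 3 lists was 0.00102, 0.0353 and 0.00785, and for each adjusted p = 0.781 with an estimated correlation. Of 34 ATF4 and amino acid response genes, 8 fell and 1 rose (19 and 1 adjusted over the list alone). Among those that fell were Trib3 (-1.07 ± 0.14), Stc2 (-1.35 ± 0.30) and Ddit3 (-1.11 ± 0.18). Stc2 ran from -1.76 to -0.8 over the fits that leave out 1 library. For this list the adjusted p of camera was 9.47e-11, and adjusted p = 0.106 with an estimated correlation. Mitochondrially encoded genes rose in 7 of 12 cases (8 adjusted over the list alone; median 1.13; camera adjusted p 1.32e-09, adjusted p = 0.751 with an estimated correlation).

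Markers of other cells moved in the same comparison. Acinar markers fell in 17 of 23 cases (21 lower and 1 higher adjusted over the list alone), with a median of -2.97 in mouse 1 and -1.22 in mouse 2, and their share of all counts was 0.0811% and 0.146% at 2G against 0.0147% and 0.0684% at 11G. Camera's adjusted p was 9.97e-22, and adjusted p = 0.542 with an estimated correlation. Ductal markers fell in 3 of 12 cases (4 adjusted over the list alone), among them Krt7 (-1.48 ± 0.16), with medians of -0.88 and -1.18 in mice 1 and 2. Their share of all counts was 0.278% and 0.551% at 2G against 0.285% and 0.306% at 11G, so it did not fall in mouse 1. Of 15 stellate markers 1 fell, Acta2 (-2.04 ± 0.39), or 3 when adjusted over the list alone. For these lists camera gave an adjusted p of 8.88e-05 and 0.00121, against adjusted p = 0.751 and adjusted p = 0.781 with an estimated correlation. Of 8 delta and PP cell markers Casr (1.36 ± 0.33, 2.10 without 2G mouse 1) and Sst (0.87 ± 0.21) rose. Adjusted over the list alone, 2 were higher and 1 lower. Camera's adjusted p was 0.0419, or 0.152 without the block, and adjusted p = 0.751 with an estimated correlation. Over the fits that leave out 1 library Casr ran from 0.81 to 2.10 and Sst from 0.72 to 1.01, and neither call held across them. The lists of calcineurin and NFAT, glucose responsive and lipogenic, glycolysis, unfolded protein response, ion channel, alpha cell, endothelial, macrophage and immune, Schwann and neural, cell cycle, heat shock, hypoxia, inflammatory and ribosomal protein genes did not pass camera in 11G, with adjusted p from 0.0517 (endothelial) to 0.937 (hypoxia).

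**Figure D1:**
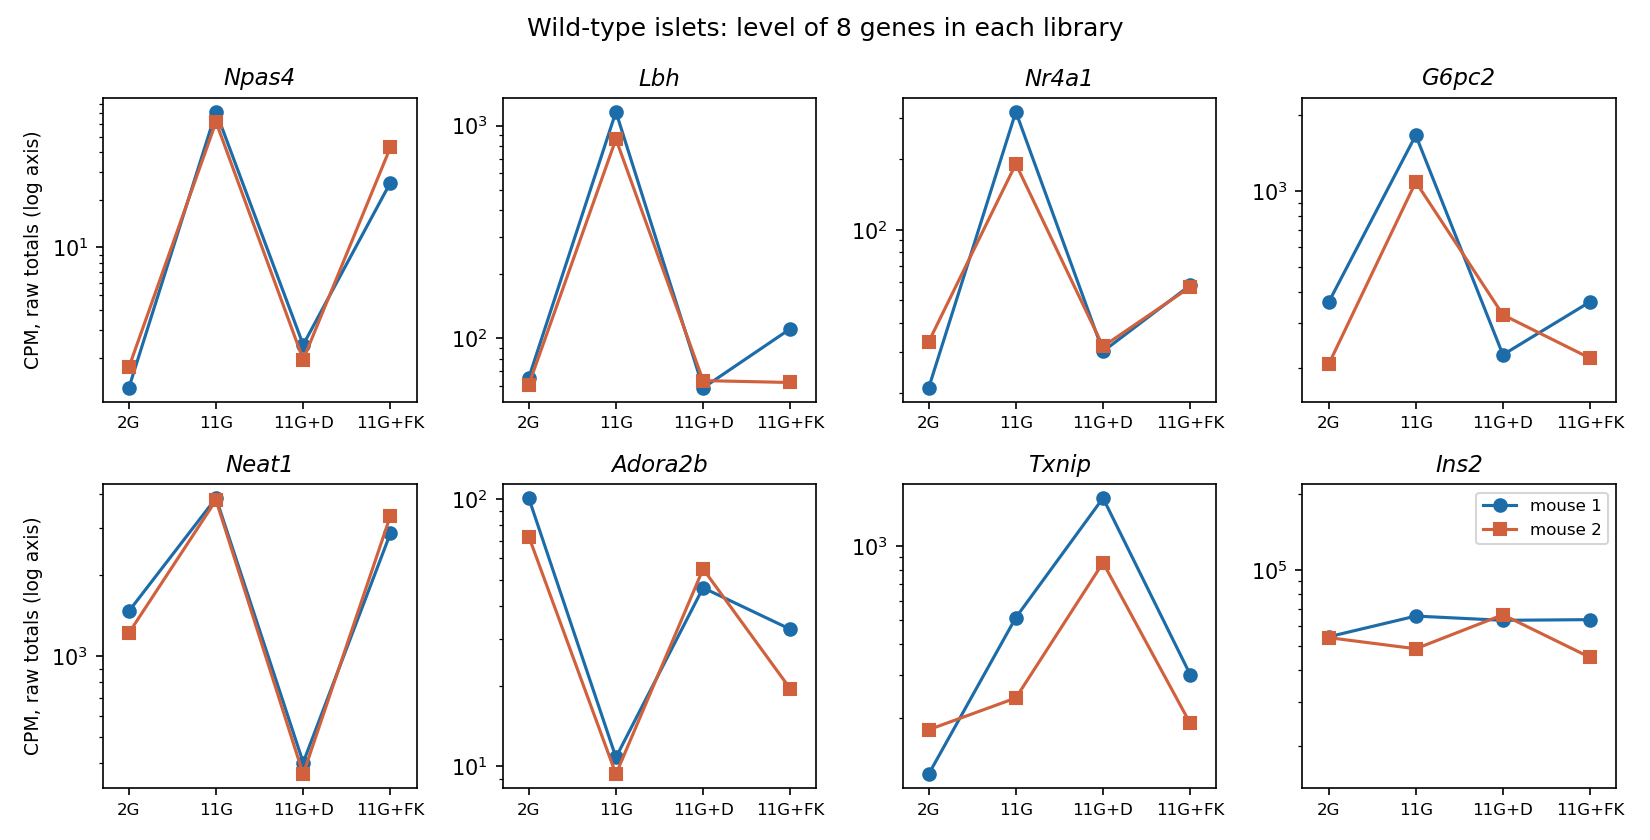
CPM over raw library totals, without TMM factors (log axis), of 8 genes in the 8 wild-type libraries, 1 line per mouse over the 4 conditions. Npas4, Lbh, Nr4a1 and G6pc2 were high at 11G in both mice, Neat1 was low with diazoxide and Ins2 lay between 44900 and 66300 CPM.

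The comparison of 11G+D with 11G asked which transcripts follow the membrane potential at high glucose. With diazoxide Npas4 fell by 4.95 on the log2 scale (± 0.30, n = 2 mice), to 2.41 and 2.01 CPM, and Lbh fell by 4.04 (± 0.26), to 58.2 and 65.0 CPM. Neat1, a nuclear noncoding RNA that builds paraspeckles, fell from 4170 and 3700 CPM to 400 and 375 CPM (-3.34 ± 0.22). Nr4a1 (-3.07 ± 0.30), Fos (-2.15 ± 0.40) and G6pc2 (-2.26 ± 0.32) fell as well. Without 11G mouse 1 Nr4a1 was at -2.47 and Fos at -1.56, not past the test (Fos passed in 2 of 4 such fits), and G6pc2 was at -1.66 without 11G+D mouse 1 and -3.03 without 11G+D mouse 2. Adora2b rose by 2.34 ± 0.24, Txnip by 1.66 ± 0.35, and the transcription factor Rfx6 by 1.90 ± 0.24. Over the fits that leave out 1 library Txnip ran from 1.26 to 2.16. The adjusted p of edgeR's quasi-likelihood test was 0.000104 for Npas4, 0.000135 for Neat1 and 0.0324 for Txnip. Ins1, Ins2, Gcg, Sst, Egr1 and Rcan1 did not pass (-0.59 to 0.18).

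Diazoxide changed 610 genes, 214 higher and 396 lower, of which 84 and 231 changed at least 2-fold. Other large decreases were in Abhd16b, Zdhhc22, Spsb4, Slc6a19os, Tmem212 and Rgs2 (-6.48 to -3.06). Abhd16b was at 0.105 and 0.118 CPM with diazoxide, and Slc6a19os is an antisense gene whose reads cannot be told from those of its partner without strand. Other large increases were in Igkc, Tcp10b, Usp29, Ttc25, Cyp4f39, Sh2d5, Aqp4 and Galr2 (1.92 to 3.60), with Igkc and Tcp10b uncertain as members of gene families. Igkc was near the floor at 11G, at 0.0909 and 0.0537 CPM over raw library totals. Without the mouse block 59 genes passed (50 lower), and leaving out 1 library gave 45 (11G mouse 1), 220 (11G+D mouse 1), 120 (11G mouse 2) or 765 (11G+D mouse 2). The acinar covariate left 150. Without 11G+D mouse 1 Igkc was at 2.73, Usp29 3.69, Sh2d5 1.19, Abhd16b -5.44, Zdhhc22 -3.98, Slc6a19os -5.52 and Rgs2 -2.40, and without 11G+D mouse 2 Usp29 was at 1.43, Sh2d5 2.69, Abhd16b -7.17, Zdhhc22 -5.42 and Rgs2 -3.80. Igkc and Usp29 passed in 1 of the 4 such fits.

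By group, 12 of 39 immediate early genes and 12 of 29 CREB and cAMP responsive genes fell with diazoxide and none rose (18 in each when adjusted over the list alone). The lists had a camera adjusted p of 3.73e-16 and 7.88e-16, against adjusted p = 0.728 and adjusted p = 0.331 with an estimated correlation. Exocytosis genes fell in 4 of 29 cases (5 adjusted over the list alone), including Vamp2 (-0.83 ± 0.14) and Syt5 (-0.88 ± 0.16), and cholesterol synthesis genes in 3 of 25 (4 adjusted over the list alone). In camera the adjusted p was 0.0131 and 0.0249, and for both adjusted p = 0.728 with an estimated correlation. Nupr1 (-0.97 ± 0.16) and Chac1 (-0.77 ± 0.16) of the ATF4 list fell (5 adjusted over the list alone; camera adjusted p 0.00139, adjusted p = 0.331 with an estimated correlation). Of 31 inflammatory genes 4 rose, among them Csf3 (1.04 ± 0.17) and Il6 (0.84 ± 0.19) (5 higher and 2 lower adjusted over the list alone; camera adjusted p 0.0332, 0.172 without the block, adjusted p = 0.728 with an estimated correlation). Camera also passed the unfolded protein response (median -0.23), ribosomal protein (0.27), mitochondrially encoded (0.41) and stellate (0.45) lists with no member past the threshold, and for each adjusted p = 0.728 with an estimated correlation. The stellate median was 1.05 in mouse 1 and -0.22 in mouse 2. Acinar markers had a median of 1.39 in mouse 1 and -0.32 in mouse 2, with no member past the threshold (camera adjusted p 0.0105, 0.235 without the block, adjusted p = 0.728 with an estimated correlation). Of the calcineurin and NFAT list, which did not pass, Nfatc2 rose (1.20 ± 0.19) and Irs2, an insulin receptor substrate, fell (-1.38 ± 0.25).

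The comparison of 11G+FK with 11G asked which transcripts need calcineurin at high glucose. With FK506 Lbh fell by 3.63 on the log2 scale (± 0.25, n = 2 mice), to 110 and 59.7 CPM. Rgs2, a regulator of G protein signalling (-2.74 ± 0.35), Nr4a2 (-2.36 ± 0.23), G6pc2 (-2.32 ± 0.32), Nr4a1 (-2.23 ± 0.29) and Prlr, the prolactin receptor (-1.85 ± 0.24), also fell. Without 11G mouse 1 Rgs2 was at -2.12 and Nr4a1 at -1.61. Over the 4 fits that leave out 1 library G6pc2 ran from -2.57 to -2.11, Nr4a2 from -2.69 to -1.99 and Prlr from -1.90 to -1.81. No FK506 call, higher or lower, held in all of these fits. Csf3 (1.14 ± 0.17) and Dbp, a clock-controlled transcription factor (1.13 ± 0.14), were the genes that rose. Npas4 (-1.07 ± 0.24, 25.6 and 41.0 CPM) and Rcan1 (-0.71 ± 0.17), did not pass the test. By edgeR's quasi-likelihood test the adjusted p was 0.000886 for Lbh, 0.0152 for Nr4a1, 0.149 for Npas4 and 0.171 for Rcan1. With FK506 Ins1, Ins2, Gcg, Sst, Fos, Egr1 and Txnip did not pass either (-0.87 to 0.51).

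FK506 changed 37 genes, 35 lower and 2 higher. Abhd16b, Megf9, Spsb4 and Rasgrp1 were the other large decreases (-5.07 to -2.08). Increases named by size alone, none of them past the test, were in Sncg, Vip, Mmp10, Adora2b, Npy, Ankrd37, Lgals4 and Wnt4 (1.11 to 1.67). Without the mouse block 1 gene passed, Lbh, and DESeq2 called 224 (56 higher, 168 lower). Leaving out 1 library gave 1 (11G mouse 1), 1 (11G+FK mouse 1), 11 (11G mouse 2) or 0 (11G+FK mouse 2, where edgeR gave 613 genes at an unadjusted p under 0.05), and the acinar covariate left 14.

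Of 29 CREB and cAMP responsive genes 5 fell with FK506 (11 lower and 1 higher adjusted over the list alone; median -0.64), including Irs2 (-1.78 ± 0.26); the adjusted p of camera was 4.88e-17, and adjusted p = 0.204 with an estimated correlation. Immediate early genes fell in 3 of 39 cases (8 adjusted over the list alone). The 3 were Nr4a1, Nr4a2 and Rgs2, which also stand in the list of CREB and cAMP responsive genes. For the immediate early list camera's adjusted p was 0.00119, and adjusted p = 0.687 with an estimated correlation. In the calcineurin and NFAT list 1 of 28 genes fell, Irs2 (3 adjusted over the list alone), and camera's adjusted p was 0.132. G6pc2 was the 1 of 35 β-cell genes that fell (3 adjusted over the list alone; camera adjusted p 0.000367, adjusted p = 0.687 with an estimated correlation). Inflammatory genes had a median of 0.47, with Csf3 past the threshold and 14 of 31 higher when adjusted over the list alone, and ATF4 genes a median of 0.33, with none past it and 5 of 34 adjusted over the list alone. Camera's adjusted p was 9.68e-10 for both, against adjusted p = 0.194 and adjusted p = 0.126 with an estimated correlation. Camera also passed the ribosomal protein, mitochondrially encoded, Schwann, unfolded protein response, endothelial and alpha cell lists with no member past the threshold, and for each adjusted p = 0.687 with an estimated correlation; without the block the adjusted p was 0.0861 for endothelial and 0.0887 for alpha cell markers. The mitochondrially encoded median was -0.01 in mouse 1 and 0.83 in mouse 2. Acinar markers had a median of -0.01.

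Many genes called with glucose were also called with the drugs, in the opposite direction. Of the 503 genes higher in 11G, 198 (39.4%) fell with diazoxide, where independent lists would share 12.4, and 87.7% had a negative log2 change with it. The 2 comparisons share the 11G libraries, so 20 simulations kept the glucose changes and gave the drug changes to unrelated genes. There 10.6 genes were shared (at most 17) and 56.7% had a negative change. Of the 35 genes that fell with FK506, 34 were higher in 11G (independent lists 1.09, simulated at most 4) and 34 fell with diazoxide (0.862, simulated at most 3). There were 33 genes higher in 11G and lower with both drugs, among them Lbh, Nr4a1, Nr4a2, Rgs2, G6pc2, Rasgrp1, Crem, Prlr, Pde5a, Atp2b4, Vdr and Scg3, named after their values were seen. Of the 275 genes lower in 11G, 41 rose with diazoxide (independent lists 3.66, simulated at most 12), Adora2b among them. Without the mouse block the 198 became 30 and the 34 shared by glucose and FK506 became 1. Leaving out 11G mouse 1, 11G mouse 2, 11G+D mouse 1 or 2G mouse 2 lowered the 198, most without 11G mouse 1. At least 1 other such fit raised it. Leaving out any library of 11G or 11G+FK lowered the 34. The ranges over all these fits are given with the processing settings below.

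**Figure D2:**
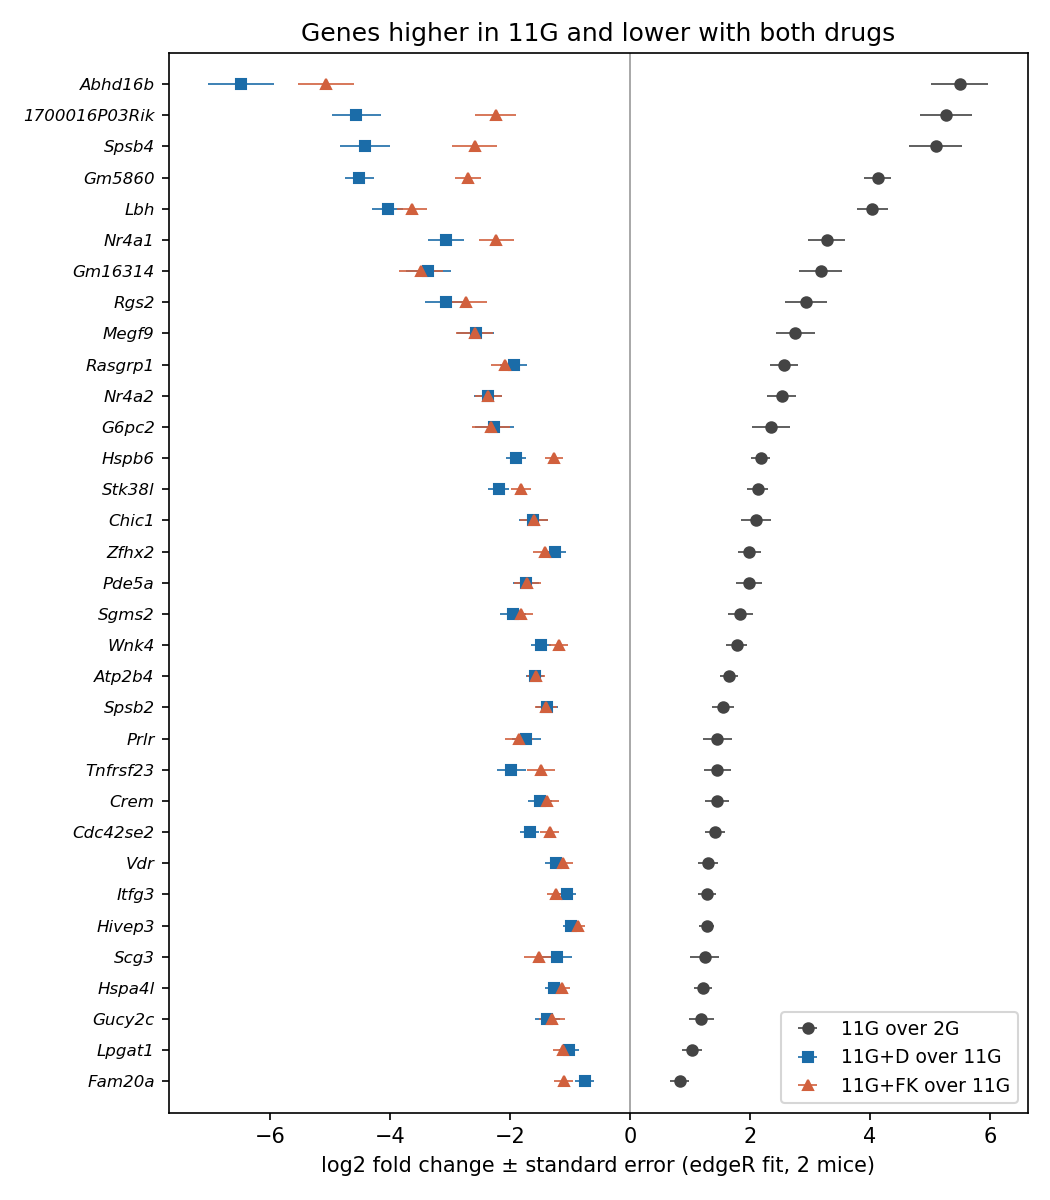
Log2 fold changes with standard errors (horizontal axis, 2 mice per group) of the 33 genes higher in 11G than in 2G and lower with both drugs; circles show 11G over 2G, squares diazoxide and triangles FK506 over 11G. All circles lie right of 0 and all squares and triangles left of it, which the selection sets.

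Across genes, which are not independent replicates, the glucose change of mouse 1 correlated by -0.16 with the diazoxide change of mouse 2, and the reverse pairing gave -0.33 (Spearman -0.13 and -0.34). With FK506 the values were -0.10 and -0.33 (Spearman -0.11 and -0.36). These pairs share no library, and unchanged simulated groups gave 0.001 and -0.001. For changes averaged over both mice the correlation was -0.49 for diazoxide and -0.48 for FK506, against -0.50 and -0.49 simulated from shared libraries alone. The covariance was -0.165 and -0.132, against -0.06 simulated for each. The diazoxide and FK506 changes correlated by 0.50 (simulated 0.49) with a covariance of 0.127 (simulated 0.06), and by 0.29 and 0.14 between mice. Log2 changes of mice 1 and 2 correlated by 0.44 for glucose, 0.39 for diazoxide, 0.35 for FK506 and 0.21 for light.

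FK506 and diazoxide were also compared directly. Npas4 was 14.8-fold higher with FK506 than with diazoxide (log2 difference 3.89 ± 0.29, n = 2 mice) and Neat1 7.83-fold higher (2.97 ± 0.22). Txnip was lower with FK506 (-2.31 ± 0.36), at 300 and 184 CPM against 1550 and 875 CPM, as were Aqp4, a water channel (-2.16 ± 0.22), and Pklr, a pyruvate kinase (-1.44 ± 0.25). By edgeR's quasi-likelihood test the adjusted p was 0.0009 for Npas4 and Neat1 and 0.0174 for Txnip, and Ins1, Ins2, Gcg, Sst, Fos, Egr1, Nr4a1 and Rcan1 did not pass (-0.81 to 1.51). Of the 198 genes higher in 11G and lower with diazoxide, 33 fell with FK506 and 188 (94.9%) had a negative log2 change with it, against 56.9% when the FK506 changes were simulated on unrelated genes. Of the 198, 31 differed between the drugs, all higher with FK506, a direction that selection for low values with diazoxide favors.

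Between the drugs 188 genes differed, 126 higher and 62 lower with FK506. Other genes higher with FK506 were Slc6a19os, Zdhhc22, Cyp1a1, Rem2, Mettl21b, Tmem212, Asb11 and Lrrc36 (2.33 to 3.73), and other lower genes were Ttc25, Tcp10b, Sh2d5, Zfp189, Racgap1, AA986860, Ppp1r3c and Dixdc1 (-3.14 to -1.47). Of 34 ATF4 genes 7 were higher with FK506 and none lower (22 adjusted over the list alone; median 0.51), including Ddit3 (1.51 ± 0.19), Chac1 (1.22 ± 0.16) and Trib3 (1.12 ± 0.14); the adjusted p of camera was 1.02e-20, and adjusted p = 0.0385 with an estimated correlation. Immediate early genes (2 of 39 higher, 8 adjusted over the list alone), cholesterol synthesis (1 of 25 higher, 3 adjusted over the list alone) and β-cell genes (1 of 35 lower, Rfx6, 3 adjusted over the list alone) passed camera, as did inflammatory genes (1 of 31 higher, Ccl20) and acinar markers (median -0.42, no member), each with adjusted p = 0.977 with an estimated correlation. The medians in mice 1 and 2 were 0.11 and -0.68 for β-cell genes and -1.03 and 0.15 for acinar markers. Without the block the adjusted p was 0.13 for inflammatory genes and 0.211 for acinar markers. Without the block 5 genes passed, DESeq2 called 501, and leaving out 1 library gave 486 (11G+D mouse 1), 3 (11G+FK mouse 1), 66 (11G+D mouse 2) or 3 (11G+FK mouse 2). With the acinar covariate 12 passed. Slc6a19os was at 5.28, Zdhhc22 2.50 and Sh2d5 -1.06 without 11G+D mouse 1, Zdhhc22 3.94 and Sh2d5 -2.56 without 11G+D mouse 2, and Cyp1a1 3.79 without 11G+FK mouse 1 and 1.98, not past the test, without 11G+FK mouse 2.

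The comparison of 11G+D with 2G asked what differed from low glucose at 11 mM glucose with diazoxide. The groups differ in glucose, in diazoxide and possibly in incubation, so a change cannot be credited to glucose alone. Txnip rose 7.44-fold (2.90 ± 0.37, n = 2 mice), from 118 to 1550 CPM in mouse 1 and from 179 to 875 CPM in mouse 2, and its log2 change was 2.24 without 2G mouse 1 and 3.77 without 2G mouse 2. Aqp4 rose by 3.41 ± 0.24 and Pdx1, a β-cell transcription factor, by 1.42 ± 0.24. The ATF4 pathway genes Ddit3 (-1.65 ± 0.19), Chac1 (-1.40 ± 0.16) and Trib3 (-1.38 ± 0.14) fell, as did the metallothioneins Mt2 (-2.56 ± 0.27) and Mt1 (-2.23 ± 0.28), whose reads could be shared. Npas4 (0.55 ± 0.34) and Nr4a1 (0.21 ± 0.29) did not pass the test, nor did Ins1, Ins2, Gcg, Sst, Fos, Egr1 and Rcan1 (-0.97 to 0.57). By edgeR's quasi-likelihood test the adjusted p was 0.00526 for Txnip and 0.00292 for Trib3. Of the 503 genes higher in 11G than in 2G, 112 were also higher here (independent lists 14.7), and of the 275 lower genes 106 were also lower (6.34). Both comparisons use the 2G libraries, and simulations with the 11G+D changes on unrelated genes shared at most 23 and 11.

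In this comparison 840 genes changed, 469 higher and 371 lower. Other large changes were increases in Tcp10b, Ttc25, Ptger3, Myl7, Ffar3, Tmem95, Kcnab3 and Rprml (2.38 to 3.05) and decreases in Hpgd, Krt80, Wnt7a, Kcnk13, Samd5, Cyp1a1, Angptl4 and Try5 (-3.07 to -2.07). ATF4 genes fell in 18 of 34 cases (25 adjusted over the list alone; median -0.68), with camera's adjusted p 5.10e-24 and adjusted p = 0.0309 with an estimated correlation. Mitochondrially encoded genes rose in 7 of 12 cases (12 adjusted over the list alone; median 1.57; camera adjusted p 2.61e-20, adjusted p = 0.716 with an estimated correlation). β-cell genes (6 of 35 higher, 1 lower, the same adjusted over the list alone), immediate early genes (4 of 39 lower, also adjusted over the list alone), ductal markers (2 of 12 lower, 4 adjusted over the list alone) and ribosomal protein genes (median 0.18, no member) passed camera, each with adjusted p = 0.921 with an estimated correlation. The medians in mice 1 and 2 were 0.29 and -1.28 for ductal markers and 0.48 and -0.10 for ribosomal protein genes. Acinar markers fell in 7 of 23 cases (21 lower and 1 higher adjusted over the list alone; median -1.55; camera adjusted p 1.01e-13, adjusted p = 0.921 with an estimated correlation). Without the block 10 genes passed, and leaving out 1 library gave 1140 (2G mouse 1), 1139 (11G+D mouse 1), 246 (2G mouse 2) or 294 (11G+D mouse 2). With the acinar share as a covariate 0 genes passed (1415 at an unadjusted p under 0.05). Kcnab3 was at 1.65, Hpgd -3.98, Wnt7a -3.68 and Samd5 -2.87 without 11G+D mouse 1, and Hpgd -2.26 and Wnt7a -1.68 without 11G+D mouse 2. Cyp1a1 was at -1.21 and Try5 -0.88 without 2G mouse 1, and Cyp1a1 -2.70, Angptl4 -1.29 and Try5 -2.98 without 2G mouse 2. Tmem95 ran from 2.19 to 2.71. The calls of Tmem95, Cyp1a1 and Try5 did not hold in most of these fits.

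Light was compared with no light in ChR2 islets to drive electrical activity, and the labels give no glucose concentration for these islets. Under light Fosb rose 12.1-fold (log2 change 3.60 ± 0.55, n = 2 mice), Npas4 5.56-fold (2.48 ± 0.35), Fos 5.00-fold (2.32 ± 0.20) and Egr1 by 2.38 ± 0.28, all transcription factors of the immediate early response. Fosb went from 10.9 to 41.7 CPM in mouse 1 and from 1.77 to 94.2 CPM in mouse 2. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) went from 15.4 and 11.4 CPM to 70.5 and 62.5 CPM. Nr4a1 rose by 1.56 ± 0.18, the lactate exporter Slc16a3 by 1.88 ± 0.22 and Ldha, lactate dehydrogenase, by 1.22 ± 0.18. The matrix metalloprotease Mmp7 fell (-2.39 ± 0.33), as did the β-cell transcription factor Nkx6-1 (-0.75 ± 0.15). By edgeR's quasi-likelihood test the adjusted p was 2.18e-05 for Fos, 0.00154 for Npas4 and 0.0216 for Nkx6-1. Ins1 (0.11 ± 0.20), Ins2 (0.02 ± 0.22), Gcg (0.04 ± 0.17), Sst (-0.23 ± 0.16), Txnip (-0.18 ± 0.17) and Rcan1 (-0.08 ± 0.18) did not pass.

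Light changed 128 of 15171 genes, 91 higher and 37 lower. Apold1, Ak4, Ccl3, Hspa1b and Hilpda were among the largest increases (1.81 to 2.36), and Serpinb6b, Ighm, Ankrd1, Scara3, Igkc, Dmbt1, Wnt7b, Clps and Cela3b the largest decreases (-2.38 to -1.55) after Mmp7. Hspa1b shares reads with its near-identical copy Hspa1a. Without the mouse block edgeR called 0 genes (654 at an unadjusted p under 0.05, and DESeq2 with the block called 86), and with all 12 libraries in 1 fit 6 genes. Leaving out a library of the light experiment was possible in that fit alone, where either library of mouse 1 gave 29 genes against its 6, and either of mouse 2 gave 0 (1187 and 1184 at an unadjusted p under 0.05). In the same fits Fosb had a log2 change of 5.72 without the no light library of mouse 1 and of 1.92, not past the test, without either library of mouse 2. Egr1 was at 3.25 and 1.50 in the same 2 cases. With the mouse block, leaving out either library of a mouse leaves the light change to the 2 libraries of the other mouse. The 4 fits therefore hold 2 light changes per gene, 1 for each mouse. Npas4 ran from 1.90 to 2.98 and Fos from 2.18 to 2.44 over the 4 fits. Of the called genes that the rule named, only Fosb, Egr1, Apold1 and Nfkbia held their calls in any of them. Without the light library of mouse 1 Hspa1b was at 0.86, Dmbt1 -2.46, Clps -2.85 and Cela3b -2.67, and Igkc was at -1.22 without the no light library of mouse 1. Without either library of mouse 2 they were at 2.73, -1.14, -0.84, -0.65 and -2.55 in that order.

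Of 38 immediate early genes 15 rose under light (23 higher and 1 lower adjusted over the list alone; median 0.91), and of 29 CREB and cAMP responsive genes 7 rose (12 higher and 1 lower adjusted over the list alone). Glycolysis genes rose in 3 of 24 cases, Ldha, Hk1 (0.96 ± 0.17) and Pfkfb3 (0.79 ± 0.16) (10 higher and 1 lower adjusted over the list alone). Hypoxia genes rose in 2 of 24 cases (16 adjusted over the list alone, median 0.57). Those 2 were Ldha and Pfkfb3, which stand in both lists. Heat shock genes rose in 4 of 20 cases (6 adjusted over the list alone), including Dnajb1 (0.89 ± 0.17), and inflammatory genes in 6 of 30 with 1 lower (12 and 2 adjusted over the list alone), including Nfkbia (1.19 ± 0.22; with all 12 libraries in 1 fit, 1.80 without the no light library of mouse 1 and 0.55, not past the test, without either library of mouse 2). Flt1 (0.93 ± 0.15) and Cdh5 (0.76 ± 0.16) of 14 endothelial markers rose (6 adjusted over the list alone). Camera's adjusted p for these 7 lists ran from 3.39e-42 (immediate early) to 4.68e-06 (heat shock), and for each adjusted p = 0.561 with an estimated correlation. Acinar markers fell in 3 of 23 cases (20 adjusted over the list alone), with medians of -0.34 and -2.64 in mice 1 and 2 and a share of counts of 0.0692% and 0.0492% without light against 0.0559% and 0.0126% under light (camera adjusted p 2.13e-31). Ductal (median -0.34), stellate (-0.41) and macrophage and immune markers (-0.16; Cd14 fell by 0.91) passed camera too, each of these 4 with adjusted p = 0.561 with an estimated correlation. The immune list's adjusted p without the block was 0.069. The ATF4 (median -0.20), unfolded protein response (-0.14; 0.03 and -0.34 in mice 1 and 2), ribosomal protein (-0.09) and mitochondrially encoded (0.23; -0.21 and 0.87) lists passed with adjusted p = 0.561, adjusted p = 0.767, adjusted p = 0.75 and adjusted p = 0.767 with an estimated correlation; the last had an adjusted p of 0.185 without the block.

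**Figure D3:**
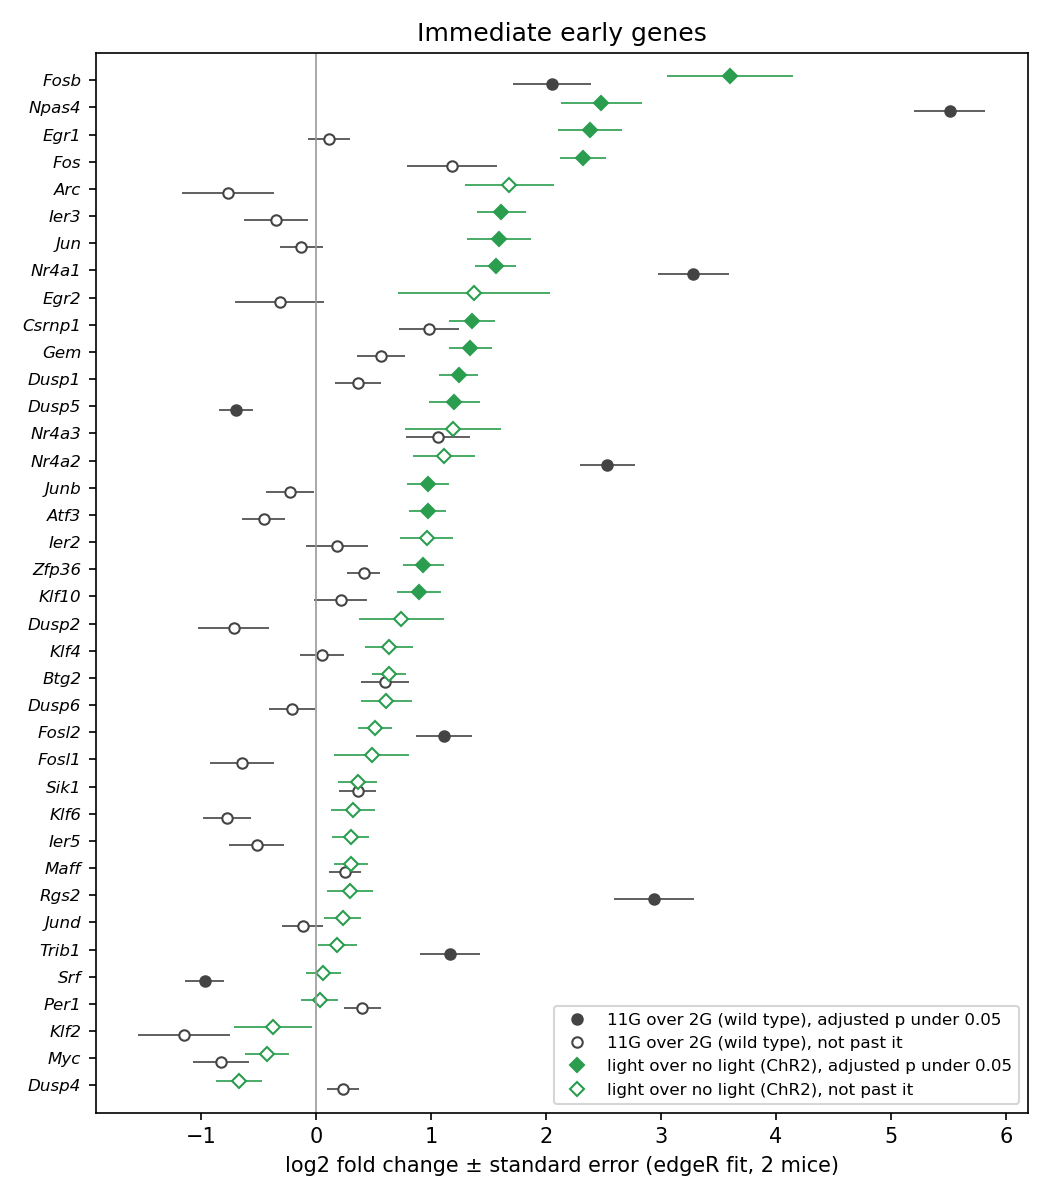
Log2 fold changes with standard errors (horizontal axis, 2 mice per group) of immediate early genes for 11G over 2G (circles) and light over no light (diamonds), filled where the adjusted p of edgeR's quasi-likelihood test was under 0.05. Fosb, Npas4 and Nr4a1 were filled in both, Fos and Egr1 under light alone, and Rgs2 and Nr4a2 in 11G alone.

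The called genes of glucose and light were compared, in experiments with no library in common. Fosb, Nr4a1, Npas4, Nfkbid, C2cd4b and Slc23a2 were higher in both, 6 genes where independent lists would share 2.97 (Fisher's exact test, one-sided p = 0.077). Of the 37 genes lower under light, 15 (40.5%) were lower in 11G too (independent lists 0.68, Fisher's exact test, one-sided p = 4.1e-17). They included Adora2b, the acinar genes Cela3b and Ctrl, and Igkc and Ighm. Fisher's test takes genes as independent and does not measure the spread between mice. Acinar markers, for instance, had an estimated inter-gene correlation of 0.63 in 11G against 2G. Dusp5 and Errfi1 were lower in 11G and higher under light. Of the genes lower with diazoxide 8 were higher under light (independent lists 2.38), among them Fos, Gem, Csrnp1 and Rasd1. Across 14972 genes the glucose and light changes correlated by 0.22 (Pearson) and 0.15 (Spearman), and genes are not independent replicates. Without the block no gene was shared in either direction, since edgeR then called 0 genes with light. Leaving out a wild-type library took the 6 to 4 (2G mouse 1), 2 (11G mouse 1), 9 (2G mouse 2) or 4 (11G mouse 2), and the 15 to 19, 2, 8 or 9 in the same order. With all 12 libraries in 1 fit, which leaving out a light-experiment library needs, 1 gene was shared higher and 0 lower. From there, leaving out either light-experiment library of mouse 1 gave 5 and 2, and either of mouse 2 gave 0 and 0.

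In the authors' deposited tables, at their adjusted p under 0.05, 224 genes in mouse 1 and 344 in mouse 2 changed in 11G, and the authors' deposited tables shared 56 higher and 32 lower genes between mice (independent lists 1.30 and 0.61). The authors' deposited tables called 268 and 103 genes with diazoxide, of which 11 higher and 46 lower were shared. For FK506 the authors' deposited tables called 26 and 56 genes with 14 shared lower and 0 shared higher, and for light 90 and 137 with 5 shared in each direction. Each of these calls compares 1 library with 1 library, not the conditions.

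**Figure D4:**
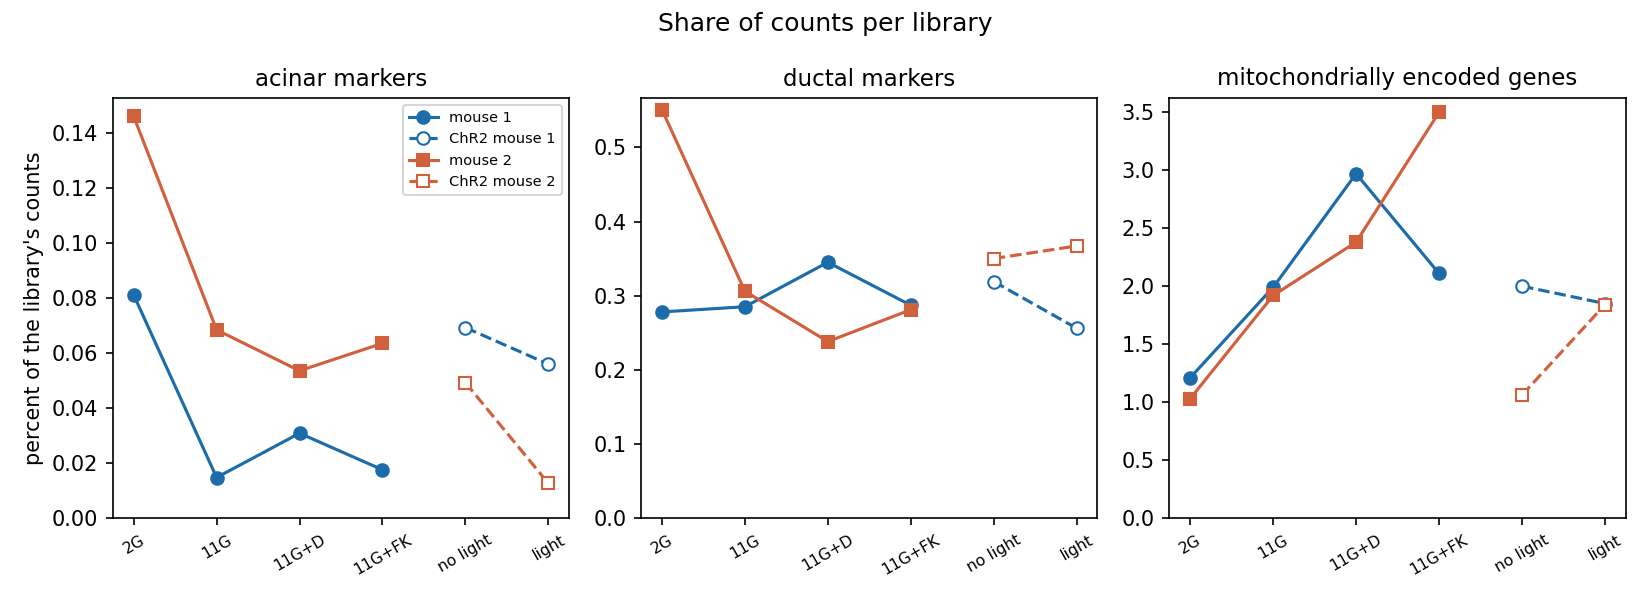
Percent of each library's counts taken by acinar markers, ductal markers and mitochondrially encoded genes, 1 line per mouse (filled, wild type; open, ChR2). The acinar share was higher at 2G than at 11G in both mice, 0.0811% and 0.146% against 0.0147% and 0.0684%.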

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

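All explanatory tests in this part were chosen after the results were seen, and 4 of the 6 were revised after a first run. The acinar carry-over test first set the largest ratio between mice against the smaller 2G over 11G ratio, a form that favored carry-over, and was replaced. The direct comparison of the drugs was planned, and it drew attention to genes whose response differed between them. By edgeR's quasi-likelihood test 188 genes differed between FK506 and diazoxide, and 59 of the genes called both with diazoxide and between the drugs had an FK506 change of the opposite sign in both mice. None of those FK506 changes passed the test (lowest adjusted p 0.198). On the log2 scale, FK506 over diazoxide, the difference was 3.89 for Npas4, 2.97 for Neat1, -2.31 for Txnip and -2.16 for Aqp4.

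The fall of Neat1 with diazoxide was weighed first. A lower share of nuclear RNA in those libraries would lower other nuclear noncoding RNAs about as much, but the median of Malat1, Xist, Kcnq1ot1, Meg3, Rian and Mirg was -0.68, and the lowest of them was Mirg at -1.32, against -3.34 for Neat1. A single aberrant library is argued against by the fits that leave out 1 library, in which the smallest change was -3.30 and the largest adjusted p of edgeR's quasi-likelihood test was 0.0018. A dependence of Neat1 on membrane potential, found on these 4 libraries, would raise it in 11G over 2G, where it rose (1.56 ± 0.21, edgeR adjusted p 0.0045, with the 11G libraries shared), and under light, where it went from 728 to 995 CPM in mouse 1 and from 1240 to 183 CPM in mouse 2 (raw-total CPM; log2 change -1.18 ± 0.47, edgeR adjusted p 0.333). That leaves the dependence open, along with other actions of diazoxide, which were not tested.

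Acinar markers were lower in 11G than in 2G. Electrical activity as the whole cause would bring them back to the 2G level with diazoxide, but their median in 11G+D over 2G was -1.55, and -1.48 in each mouse. Exocrine tissue carried over in different amounts may account for the fall: the acinar share of the 2 mice of a condition differed 2.70-fold on average (geometric mean of 1.80 at 2G, 4.65 at 11G, 1.74 with diazoxide and 3.63 with FK506), against 3.43-fold between 2G and 11G (5.52 and 2.13 in mice 1 and 2), which leaves carry-over and condition unresolved. With the acinar share as a covariate, 0 genes passed in 11G against 2G by edgeR (928 at an unadjusted p under 0.05), but condition and mouse explain 91.4% of the variance of that share, so the standard error of Npas4 grew from 0.31 to 0.70 while its change went from 5.51 to 5.32. Nr4a1 went from 3.28 ± 0.31 to 1.87 ± 0.44, and incubation of the 11G islets stays open as well.

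Heat shock and hypoxia genes were higher under light. Light or handling apart from the channel cannot be told apart from the channel itself, because no islets without the channel were lit; the lowest median of the lists in a mouse was 0.19. Electrical activity, which 11G could also raise, was tested on the 44 members of these lists, whose median was 0.47 under light and -0.02 in 11G over 2G. The members spread by 0.56 (SD) in 11G over 2G and the experiments differ in length, so this does not decide between them. Hspa1a, at 2.97 in mouse 1 and 0.12 in mouse 2, did not pass the test (1.67 ± 0.44).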

How the results depend on the processing

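The acinar marker share as a covariate was the setting chosen after the data were examined; the others were planned. Counts of changed genes are given in the order 11G, diazoxide, FK506, light, FK506 against diazoxide, and 11G+D against 2G, with main values of 778, 610, 37, 128, 188 and 840. Without the replicate block they were 68, 59, 1, 0, 5 and 10, where edgeR gave 654 genes for light at an unadjusted p under 0.05 and DESeq2 called 86 with the block; the cause was not tested. With no filter on low counts they were 1672, 1085, 309, 419, 617 and 1573. DESeq2 gave 1315 for 11G, 224 for FK506 and 501 for FK506 against diazoxide, and all 12 libraries in 1 fit gave 58 for FK506 and 6 for light. With the acinar covariate they were 0 (928 at an unadjusted p under 0.05), 150, 14, not run for light, 12 and 0 (1415). Leaving out 1 library gave 42 to 1405, 45 to 765, 0 to 11, 0 to 29, 3 to 486 and 246 to 1140; those for light had to use all 12 libraries in 1 fit, so the 0 to 29 stands against 6, not 128. The lone library left in a group is assumed to vary like the others. These fits have fewer samples, and in those for light the light change rests on 1 mouse.

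Of the genes higher in 11G, 198 were lower with diazoxide and 34 with FK506. These became 30 and 1 without the block, 330 and 159 with no filter, and 0 and 0 with the covariate, while DESeq2 gave 128 for the latter. Leaving out 1 library gave 20 to 215 and 0 to 35. The 6 genes higher and the 15 lower in both 11G and light became 0 and 0 without the block, 34 and 74 with no filter, and 1 and 0 with all 12 libraries in 1 fit. RLE size factors gave 24 for the latter, and leaving out 1 library gave 0 to 9 and 0 to 19, where light libraries were left out of the fit with 1 and 0. The cause was not tested.

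With genes of a mean of at least 5 FPKM, the correlation between mice was 0.65 for 11G, 0.64 for diazoxide, 0.66 for FK506, 0.27 for light, 0.43 for FK506 against diazoxide and 0.36 for 11G+D against 2G. Between mice, the glucose and diazoxide changes then correlated by -0.32 and -0.56, the glucose and FK506 changes by -0.26 and -0.57, and glucose and light by 0.18. The covariate reversed 4 named genes, Reg1 (0.12) and Cela3b (0.37) in 11G, and Try5 (0.17) and Prss2 (0.07) in 11G+D against 2G, none of them past the test there.

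Of 231 calls of named genes, 32 passed without the block and 199 lost significance, while all 231 passed with no filter. DESeq2 kept 220, and leaving out 1 library kept 428 and lost 496 over all such fits. Of 61 calls of gene lists, an estimated correlation kept 2, fry 4 and the fit without the block 52. Read depth limits genes with few reads, such as Abhd16b.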

Other observations

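The 91 genes higher under light had a median log2 change of 0.03 in 11G over 2G, with 56% above 0 against 48.6% of all 14972 genes tested in both experiments. In 11G+D over 11G their median was -0.15, with 71.4% below 0 against 49.3%. Single members went far from the median in 11G, such as Npas4 (5.51) and Fosb (2.05), so the medians do not say that the set lacked a response. These values were computed after the results were seen.

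The libraries differed in sex-linked transcripts. Ddx3y, a Y-linked gene, was at 94.5 and 65.2 CPM in the no light and light libraries of ChR2 mouse 2, where Xist was at 124 and 153 CPM. In the other 10 libraries Ddx3y reached at most 0.122 CPM and Xist ran from 641 to 1850 CPM. The labels give no sex, and all libraries of a mouse carried the same pattern. Whether ChR2 mouse 2 was a male or a pool of both sexes is not known.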
